A study of Mus musculus with 6 samples.

How the data were processed

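RNA from sorted bone marrow-derived macrophages was sequenced after co-culture with the mEC25 line in contact (3 libraries) or across a transwell (3 libraries). Per the labels, total RNA was taken with Trizol and turned into mRNA-seq libraries with a kit the labels do not name. Groups and replicate numbers were taken from the sample titles. The comparison, its test, 31 gene lists and the rule for named genes were fixed before the data were examined.

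The authors deposited raw read counts per Ensembl gene for each of the 6 libraries, per the file headers, with 56691 genes. The deposited table also gives FPKM per library, and of values with a count above 100 a share of 99.93% lay within 1% of the value computed from the count, the given exonic length and the library total. The submitters' processing notes name GRCm38 and mm10. The aligner, the counter, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be split in unknown ways. Of 52073 gene IDs shared with GENCODE M21, which is on GRCm38, 1472 had the same start and end in the deposited table, so no coordinate of that table is printed and positions come from GENCODE M21 by gene ID. Gene symbols and pathway names are those of the deposited table.

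Library totals were 22563835, 20911880 and 22200437 counts in contact and 18895818, 18173192 and 18569930 in transwell libraries. Replicates were compared by a chi-square of their counts, which lay between 6.376 and 25.18 per degree of freedom, so no pair of libraries agreed within sampling noise. The 10 most abundant genes took 12.3 ± 0.427% of counts in contact and 13.9 ± 0.83% in transwell libraries (SD, n = 3).

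The plan named limma on log2(FPKM + 1), with counts to take its place if present, and they were. Genes were filtered with filterByExpr (minimum count 10), which kept 14113, libraries were scaled with TMM, and contact was compared with transwell by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The test is two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are contact minus transwell, with a standard error computed as the absolute change over the square root of the test's F statistic. For genes with few transwell counts, such as Krt5 with 12 in all, it may be smaller than the counting error. Against groups with a count of 0, folds are lower bounds at 3 counts over the group. Genes with 1 to 3 transwell counts are given as levels. The common biological coefficient of variation was 0.1225.

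Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry, over 30 lists. Where a symbol had several rows the row with the highest total count was taken. The named genes are the 12 largest rises and 12 largest falls on the log2(FPKM + 1) scale among genes past the threshold, with groups that do not overlap, a mean of at least 5 FPKM in the higher group and a symbol that is not a Gm number, a Rik clone, an accession or a pseudogene. To these come up to 4 members of each list and 14 genes given always. Cxcl10 and Gbp5 were named after their values were seen, as were the sex-linked and pathway genes of the closing section. Some genes that the rule takes are not reported here.

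The test was tried on simulated counts for the contact against transwell comparison with 14113 genes. It recovered 28 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 5.81% of its calls were false. Far fewer genes were changed here than the 5286 called in the data, which alters the adjusted threshold, so these shares need not hold for the data. Both lists shifted by 1.5-fold were called, and 0 of 28 others. The simulated genes varied independently of each other, so the 0 does not speak to false list calls where genes vary together.

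Alternatives were other filters, scalings, pseudocounts of 0.1 and 0.5, limma, DESeq2 1.42.0, a replicate block with and without a correction for GC content and length (lowess, span 0.3), and each library left out in turn. Markers of epithelium and mitochondrial genes were left out of another fit. Added after the data were seen were a filter on a mean transwell FPKM of at least 1 and the GC and length correction without the block. GC content, from the longest GENCODE M21 transcript, was known for 98.87% of tested genes.

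The slope of a gene on the epithelial marker level was fitted over the 3 contact libraries on the log2 scale. The level was the geometric mean of 25 called markers with a mean transwell FPKM under 0.5. Intervals of median slopes are 95% ranges of 10000 draws of list members, so they cover the choice of genes and not the spread between libraries. Expression of mEC25 cells alone was not analysed here. Figures were drawn with matplotlib 3.10.9.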

Results

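Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, grown with the macrophage growth factor M-CSF and sorted after co-culture with mEC25, a cancer cell line per the labels. In 3 libraries the macrophages had touched the cancer cells (contact), and in 3 libraries a transwell had kept the cell types apart (transwell). The contact libraries held 22563835, 20911880 and 22200437 counts and the transwell libraries 18895818, 18173192 and 18569930. The labels do not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The comparison asked which genes differ between macrophages in direct contact with the cancer cells and macrophages sharing only their medium.

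Contact libraries held high levels of the keratin transcripts Krt5, Krt14 and Krt6a, which were close to absent from transwell libraries. They also had more transcripts of the cytokine Il1b and of the enzymes of cholesterol synthesis. Interferon-induced genes and the monocyte and neutrophil attractants Ccl2, Ccl7, Cxcl3 and Cxcl5 were lower in contact libraries. Of 14113 genes tested with edgeR's quasi-likelihood test, 5286 differed at a Benjamini-Hochberg adjusted p under 0.05, 3016 higher and 2270 lower in contact. A change of at least 2-fold was fitted for 1997 of them, 1661 higher and 336 lower. The first principal component, which parted the groups, held 83.5% of the variance, and 7106 genes (50.35%) had groups that did not overlap, where chance gives 10%.

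Of the 1661 genes at least 2-fold higher, 1360 had a mean FPKM under 1 in transwell libraries and 108 had no transwell count, and of the 336 at least 2-fold lower, 149 had a mean FPKM under 1 in contact libraries. When the test was run on genes with a mean transwell FPKM of at least 1, a filter chosen after the epithelial genes were seen and which favours falls, 333 were at least 2-fold higher and 215 lower. On the FPKM scale the split of called genes moved with the scaling. It was 2873 higher and 1324 lower in limma on log2(FPKM + 1) without added scaling, and 2166 higher and 1898 lower with TMM scaling. With median-ratio scaling it was 1923 higher and 2179 lower, and after quantile normalization 1908 higher and 2443 lower. After quantile normalization 427 genes were at least 2-fold higher and 184 lower.

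**Figure D1:**
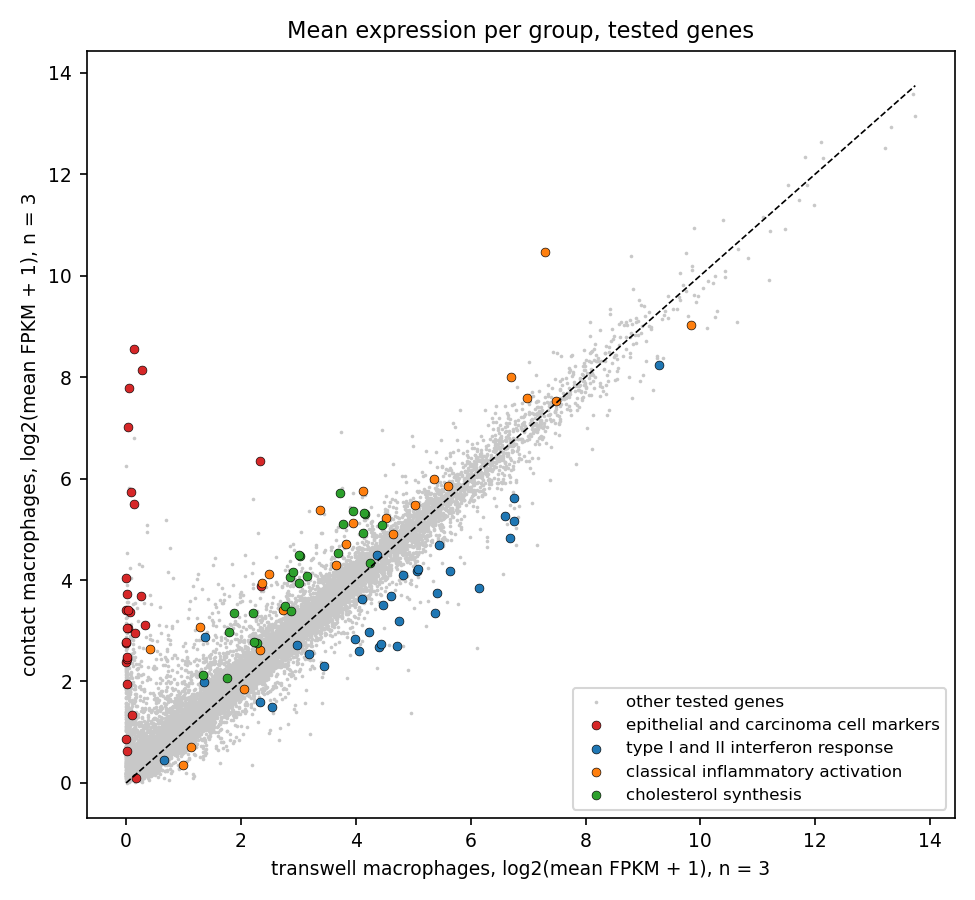
Mean expression of each tested gene in contact (vertical) against transwell macrophages (horizontal), both as log2(mean FPKM + 1) over 3 libraries, with the dashed line marking equal values. Of the 27 epithelial markers (red) called higher in contact, 25 had a mean transwell FPKM under 0.5. In contact, 22 of 24 cholesterol synthesis genes (green) were called higher and 28 of 32 interferon genes (blue) lower.

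The epithelial markers had the highest median change of the fixed lists. The basal keratin gene Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898 on GRCm38) stood at 376 ± 120 FPKM (SD, n = 3) in contact and 0.0967 ± 0.0379 FPKM in transwell libraries, a log2 change of 11.75 ± 0.36 (SE, edgeR adjusted p = 1.4e-07). Krt5 and the other genes given here with positions are annotated as protein-coding. Its partner Krt14 reached 282 ± 83.3 against 0.207 ± 0.0666 FPKM, and Krt6a 219 ± 66.3 against 0.03 ± 0.0265 FPKM. Krt17 (129 ± 37.9 against 0.0233 ± 0.0208 FPKM), Krt18 (44.2 ± 16.7 against 0.1 ± 0.0794 FPKM) and Perp, a desmosome gene (52 ± 16.7 against 0.0633 ± 0.0289 FPKM), followed. Of 28 tested markers fixed beforehand, 27 rose, none fell, and the median log2 change was 8.99, or 8.65 with the 2 members without transwell counts at their bound (camera adjusted p = 1.4e-98). With an estimated correlation the adjusted p was 0.0655. Markers took 0.318 ± 0.0939% of counts in contact and 0.00495 ± 0.00064% in transwell libraries.

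Other genes with large rises were Gsta4, a glutathione transferase gene (110 ± 29.9 against 0.0967 ± 0.0666 FPKM), Hspb1, a small heat shock protein gene (log2 change 6.73 ± 0.29), Cavin1, a caveola component (6.60 ± 0.34), and Serpinb5 (22.2 ± 5.96 against 0.0133 ± 0.0115 FPKM). Over the 3 contact libraries their slopes on the epithelial marker level were 0.90 for Gsta4, 0.98 for Hspb1 and 1.26 for Cavin1. The prolactin family gene Prl2c3 had no transwell count and was at least 1731-fold higher, against a floor of 3 counts over the group, which covers counting error only. Prl2c3 and Prl2c2 (55.3 ± 16.4 against 0.0333 ± 0.0289 FPKM) are near-identical copies, as are parts of Krt6a, Krt14 and Krt17 within their family, and how the authors' counting split shared reads is not given in the sources used here. Epcam stood at 7.34 ± 2.51 against 0.01 ± 0.0173 FPKM. Krt8, which was too low to be tested, stood at 0.307 ± 0.0611 against 0.03 ± 0.03 FPKM.

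Interferon-induced genes fell together. Of 32 members, 28 fell and 2 rose (29 and 2 adjusted over the list alone), with a median log2 change of -1.32 (camera adjusted p = 3.8e-41, and adjusted p = 0.0223 with an estimated correlation). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731 on GRCm38), which shares sequence with a neighbouring copy, dropped from 70.2 ± 4.88 to 13.4 ± 1.25 FPKM, a log2 change of -2.51 ± 0.10 (adjusted p = 3.7e-07). Usp18, a brake on interferon signalling (-2.31 ± 0.10), Zbp1, a nucleic acid sensor (-2.24 ± 0.08), and Oasl1 (-2.01 ± 0.09) fell as well. The 2 that rose, named after their values were seen, were Cxcl10, a chemokine that interferon induces (1.87), and Gbp5, a guanylate-binding protein gene (0.82).

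Genes of MHC class I presentation fell in 17 of 18 cases and rose in none, with a median of -0.61 (camera adjusted p = 3.9e-15, and adjusted p = 0.0726 with an estimated correlation). H2-T23 went from 165 ± 8.57 to 61.4 ± 1.09 FPKM, and the peptide transporter gene Tap1 from 30 ± 1.79 to 14.2 ± 0.491 FPKM. H2-T24 (-2.47 ± 0.13) and H2-Q7 (-1.94 ± 0.20) belong to a family of similar copies, so their values are uncertain. Of 12 MHC class II genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), among them H2-Eb1 (0.83 ± 0.08), H2-Ab1 (86.6 ± 5.11 against 49 ± 7.75 FPKM) and H2-Aa (0.59 ± 0.11). That list was not called (camera adjusted p = 0.188), though it was called higher under 13 of 24 alternatives, with an adjusted p of 0.0336 without transwell replicate 1 and a range of 0.00752 to 0.423.

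Inflammatory activation genes were higher in contact macrophages. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139 on GRCm38) stood at 1408 ± 39.3 against 156.9 ± 0.71 FPKM, 8.28-fold higher (log2 change 3.05 ± 0.07, adjusted p = 3.0e-08). Il12b (3.87 ± 0.25), Il6 (2.23 ± 0.16) and the prostaglandin synthase gene Ptgs2 (40.8 against 9.43 FPKM) rose too, while the nitric oxide synthase gene Nos2 fell (0.287 ± 0.0862 against 0.98 ± 0.182 FPKM). Of 24 members, 16 rose and 3 fell (16 and 4 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 9.8e-11). With an estimated correlation the adjusted p was 0.1955. Over the 3 contact libraries the rising members had a median slope of -0.14 on the epithelial marker level, on log2 scales (interval over genes -0.24 to -0.037), where 0.56 is the value computed for a rise that follows the markers in full.

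Chemokine genes went both ways, with 6 of 19 higher and 10 lower (6 and 11 adjusted over the list alone) and a median of -0.46 (camera adjusted p = 1.0e-04). With an estimated correlation the adjusted p was 0.383, and with the preset correlation the call ended under 3 scalings of FPKM. Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624 on GRCm38), a neutrophil attractant, fell from 30.2 ± 5.72 to 1.6 ± 0.536 FPKM (-4.36 ± 0.23, adjusted p = 1.4e-06). Cxcl3 (-2.63 ± 0.15), Ccl2, a monocyte attractant (-2.64 ± 0.13), Ccl7 (-2.49 ± 0.16) and Ccl12 (-3.72 ± 0.57) fell, and Cx3cl1 rose (3.54 ± 0.40), a call that ended under quantile normalization. Further large falls were Slc13a3, a dicarboxylate transporter gene (-3.79 ± 0.10), Fcrls (-3.11 ± 0.13), Susd2 (-3.21 ± 0.17), the complement gene Cfb (-2.44 ± 0.10), Bst1 (-2.26 ± 0.13) and Phf11b (-2.39 ± 0.10), which has near-identical neighbours.

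Genes of cholesterol synthesis rose in 22 of 24 cases and fell in none (23 and 0 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 6.9e-18, and adjusted p = 0.0377 with an estimated correlation). Cyp51 (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746 on GRCm38), a sterol demethylase gene, went from 12.2 ± 0.36 to 51.4 ± 4.31 FPKM, 3.87-fold higher (log2 change 1.95 ± 0.08, adjusted p = 4.4e-07). Idi1 (1.66 ± 0.16) and Fdft1 (1.44 ± 0.10), which act in the same pathway, rose with it. Of 15 cholesterol efflux and LXR target genes, 6 rose and 3 fell (6 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.272), though 2 alternatives called it higher. Its largest changes were Scd2 (1.48 ± 0.06) and Nr1h3, the gene of LXR alpha (1.21 ± 0.08).

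**Figure D2:**
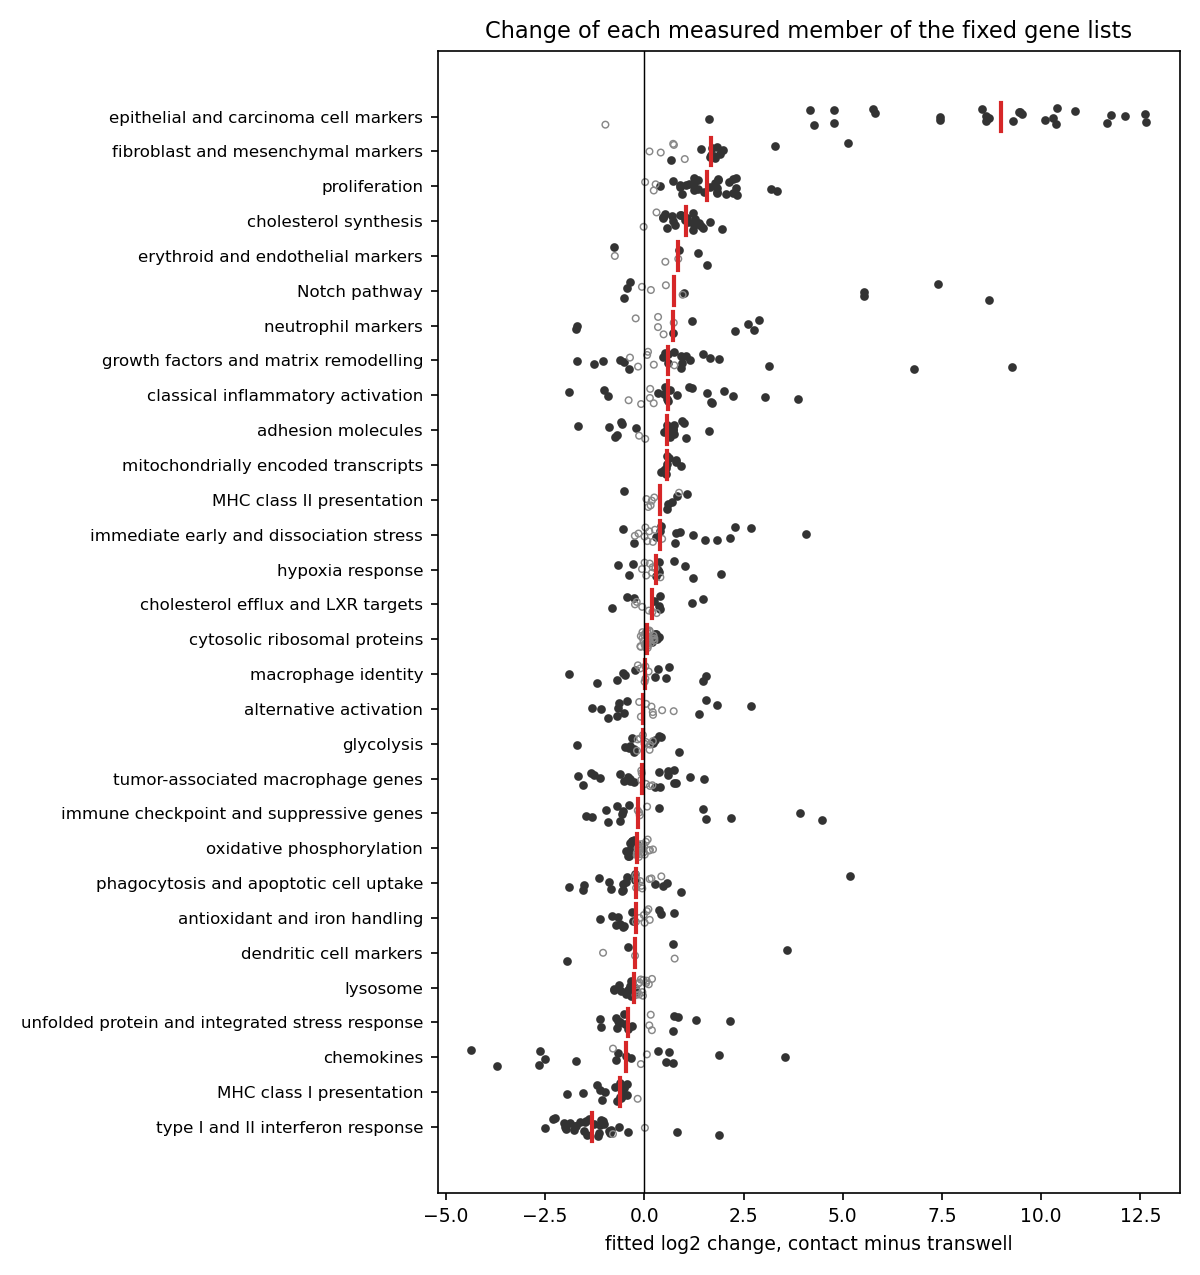
Fitted log2 change between contact and transwell macrophages (horizontal) for each measured member of the 30 tested gene lists (rows), with filled points for adjusted p under 0.05, open points otherwise and red bars at list medians. The epithelial list has the highest median, 8.99, and the interferon list the lowest, -1.32.

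Proliferation genes rose in 29 of 32 cases and fell in none, with a median of 1.58 (camera adjusted p = 2.4e-14). With an estimated correlation the adjusted p was 0.3835. The cyclin gene Ccnd1 went from 1.36 ± 0.159 to 15.1 ± 5.19 FPKM (3.35 ± 0.23), and the mitotic genes Cdc20 (3.19 ± 0.25) and Aurka (2.32 ± 0.22) rose. Across the 3 contact libraries the rising members had a median slope of 0.905 on the epithelial marker level (interval over genes 0.80 to 0.99, 0.71 for a rise that follows in full). Fibroblast and mesenchymal markers rose in 12 of 17 cases, with none lower and a median of 1.67 (camera adjusted p = 0.00264, and adjusted p = 0.540 with an estimated correlation), for example Sparc (20.6 ± 6.11 against 1.92 ± 0.916 FPKM). The rising ones had a median slope of 0.60 on the marker level (interval 0.37 to 0.86, 0.71 for a rise that follows in full).

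Growth factor and matrix genes rose in 16 of 28 cases and fell in 6 (18 and 6 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.0106). With an estimated correlation the adjusted p was 0.242, and under DESeq2 the preset-correlation adjusted p was 0.0509. The epidermal growth factor family genes Areg (6.80 ± 0.45) and Ereg (6.79 ± 2.26 against 0.01 ± 0.0173 FPKM) and Pdgfa (1.87 ± 0.13) rose, with slopes on the marker level of 0.97 for Areg, 1.17 for Ereg and 0.39 for Pdgfa. The 16 rising members had a median slope of 0.15 (interval over genes -0.014 to 0.641), where 0.508 is the value computed for a rise that follows the markers in full. Of 12 Notch pathway genes 5 rose and 3 fell, with a median of 0.76 (camera adjusted p = 0.00955, and adjusted p = 0.1955 with an estimated correlation). Jag2 (5.54 ± 0.26) and the target gene Hes1 (5.54 ± 0.26) rose, and Dll1 was at least 44.8-fold higher over a transwell count of 0. The 5 rising Notch genes had a median slope of 0.72 on the marker level (interval 0.16 to 1.25, 0.98 for a rise that follows in full). With only genes of mean FPKM at least 5 tested, the Notch median was -0.29 in edgeR and -0.22 in limma, and -0.15 with a mean transwell FPKM of at least 1, none of them called, and 9 other alternatives ended the call. Adhesion genes rose in 14 of 23 cases and fell in 7, and that list was not called (camera adjusted p = 0.188), though 3 alternatives called it higher.

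Markers of macrophage identity went both ways, with 6 of 18 higher and 6 lower, a median of 0.02, a mean of -0.02 and a lower direction by camera (adjusted p = 0.281). Adgre1, the gene of F4/80, fell from 1228 ± 83.7 to 577.8 ± 57.1 FPKM (-1.20 ± 0.09), the Fc receptor gene Fcgr1 fell (-1.91 ± 0.07) and Cd68 fell (-0.70 ± 0.08). Cd14 (1.49 ± 0.07) and Cx3cr1 (1.54 ± 0.14) rose. Csf1r, the M-CSF receptor gene, stood at 372.6 ± 26.3 against 284.2 ± 9.2 FPKM (log2 change 0.28, adjusted p = 0.0173), and Ptprc at 37.2 ± 6.28 against 22.4 ± 5.76 FPKM (0.62, adjusted p = 0.0203). The Csf1r call ended without contact replicate 1 (log2 change 0.25) or 3 (0.24) or transwell replicate 2 (0.26) or 3 (0.24). The Ptprc call ended without contact replicate 3 (0.47) or transwell replicate 3 (0.62), and in limma without a filter (0.72).

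The lists for alternative activation, tumor-associated macrophages and checkpoint genes were not called. Alternative activation genes rose in 4 of 20 cases and fell in 8 (6 and 8 adjusted over the list alone), and the median (-0.02), the mean (0.14), camera's direction (lower) and that of fry (higher) differed in sign (camera adjusted p = 0.647). Arg1 stood at 26 ± 1.05 against 45.1 ± 1.83 FPKM (-0.91 ± 0.07), Mrc1 at 21.3 ± 4.01 against 19.1 ± 4.49 FPKM (adjusted p = 0.866), and Tgm2 rose (1.55 ± 0.08). Genes of tumor-associated macrophages rose in 10 of 27 cases and fell in 11 (11 and 11 adjusted over the list alone; camera adjusted p = 0.272). Among them the lipid genes Lpl (-1.67 ± 0.13), Cd36 (-1.54 ± 0.14) and Plin2 (-1.34 ± 0.10) fell, and Spp1 (0.59 ± 0.08) and Fn1 (1.51 ± 0.12) rose. Checkpoint and suppressive genes rose in 6 of 19 cases and fell in 9, with a median of -0.16, a mean of 0.33 and a lower direction by camera (adjusted p = 0.287), and 6 of 24 alternatives called them lower. Cd274, the gene of PD-L1, fell (55.5 ± 7.54 against 78.4 ± 4.08 FPKM), while Cd276 (4.47 ± 0.35) and Havcr2 (2.19 ± 0.13) rose, with slopes on the epithelial marker level over the 3 contact libraries of 1.23 and -0.16.

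**Figure D3:**
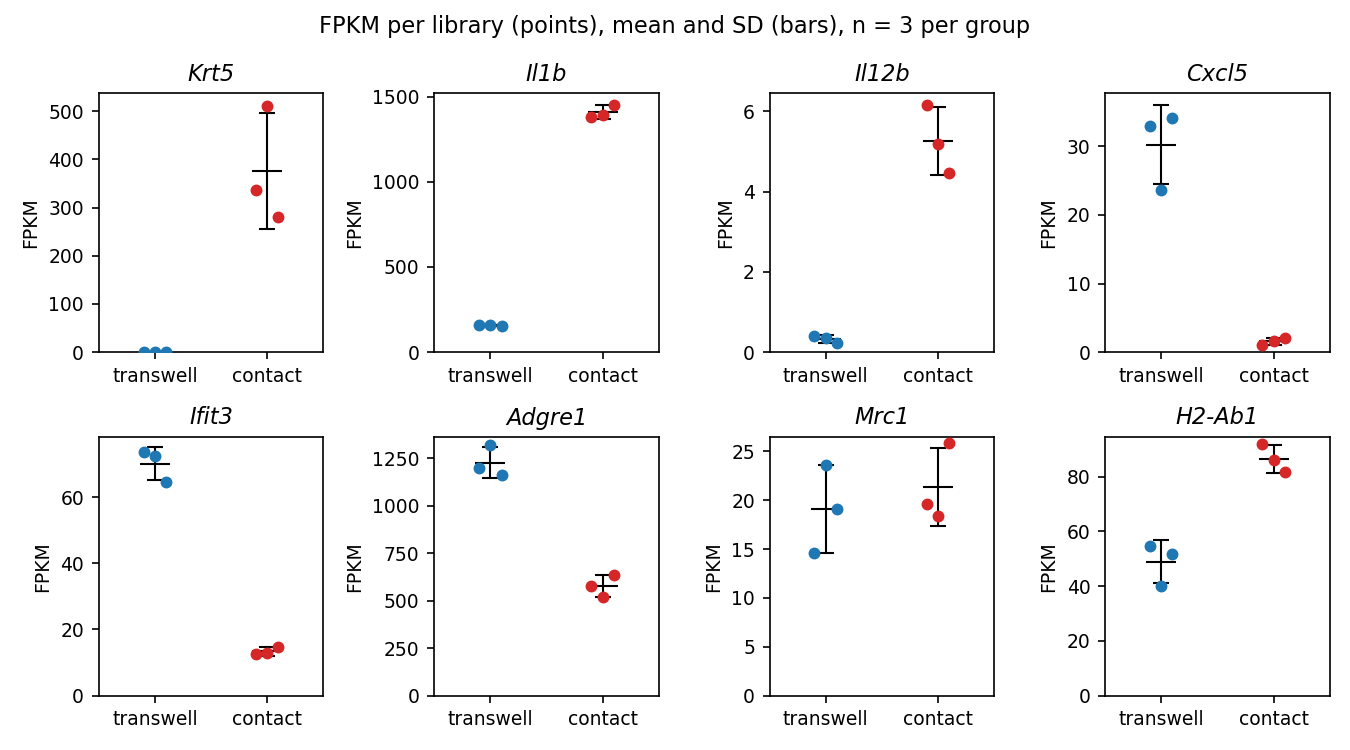
FPKM of 8 genes in each library (points, left to right replicates 1 to 3) with the mean and SD of each group of 3 (bars), every axis starting at 0. Il1b stands near 1408 FPKM in contact and 156.9 FPKM in transwell macrophages, Adgre1 near 577.8 and 1228 FPKM, and the groups overlap for Mrc1.

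Lists of uptake and degradation genes had medians a little below 0. Single phagocytosis genes changed by more, with Fcgr1 (-1.91) and Cd36 (-1.54) lower. Tyro3 was higher (5.17 ± 0.52) but near the floor, at 0.493 ± 0.203 against 0.0133 ± 0.00577 FPKM with 4 transwell counts in all. Its values in contact replicates 1 to 3 (0.43, 0.72 and 0.33 FPKM) ranked as the epithelial marker level did (0.915, 1.30 and 0.781 relative to its mean). Phagocytosis genes fell in 13 of 27 cases and rose in 5 (14 and 5 adjusted over the list alone; median -0.21, camera adjusted p = 1.3e-04, and adjusted p = 0.3835 with an estimated correlation). The Fc receptor gene Fcgr4 was among them (-1.51 ± 0.08), and the call of the list ended under quantile normalization (adjusted p = 0.0908). Lysosome genes fell in 17 of 30 cases and rose in none (19 and 1 adjusted over the list alone; median -0.26, camera adjusted p = 2.4e-04, and adjusted p = 0.479 with an estimated correlation), among them the acid lipase gene Lipa (-0.63 ± 0.09). Antioxidant and iron genes fell in 9 of 19 cases and rose in 3 (median -0.21, camera adjusted p = 0.0116, and adjusted p = 0.479 with an estimated correlation), a call that 8 alternatives ended. Hmox1, the heme oxygenase gene, fell from 1250 ± 178 to 629 ± 39.7 FPKM.

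All 10 tested mitochondrially encoded transcripts rose, with a median of 0.57 (camera adjusted p = 6.4e-04, and adjusted p = 0.479 with an estimated correlation), for example mt-Cytb (0.92 ± 0.12), and mitochondrial genes took 1.78 ± 0.039% of counts in contact and 1.14 ± 0.187% in transwell libraries. Nuclear oxidative phosphorylation genes fell in 14 of 31 cases and rose in none, with a median of -0.19 (camera adjusted p = 0.0116, and adjusted p = 0.723 with an estimated correlation), a call that ended without transwell replicate 1 (median -0.14, adjusted p = 0.0554) and under 4 other alternatives. Immediate early and dissociation stress genes rose in 13 of 24 cases and fell in 2 (15 and 2 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 3.0e-05, and adjusted p = 0.242 with an estimated correlation). Nr4a1 (2.29 ± 0.13) and Klf4 (2.69 ± 0.20) rose, as did Hspa1b (4.08 ± 0.29), which has a near-identical copy. On the epithelial marker level over the 3 contact libraries the 13 rising members had a median slope of 0.27 (interval over genes -0.016 to 0.320), where 0.584 is the value computed for a rise that follows the markers in full, with 0.95 for Klf4 and Hspa1b and 0.28 for Nr4a1. Unfolded protein and stress response genes fell in 11 of 19 cases and rose in 5 (11 and 6 adjusted over the list alone; median -0.41, mean -0.05, camera adjusted p = 0.0265, and adjusted p = 0.411 with an estimated correlation), a call that 8 alternatives ended, among them leaving out contact replicate 3 (median -0.35, adjusted p = 0.210). The chaperone gene Sdf2l1 fell (-1.11 ± 0.08), and the serine synthesis genes Phgdh (2.17 ± 0.26) and Psat1 (1.29 ± 0.17) rose, and the 5 rising members had a median slope of 0.84 on the marker level (interval -0.35 to 1.02, 0.45 for a rise that follows in full).

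The remaining lists were not called. Neutrophil markers rose in 6 of 13 cases and fell in 2 (camera adjusted p = 0.368, and called higher under 2 of 24 alternatives, with 0.00919 without transwell replicate 1 and 0.0226 in limma after quantile normalization), with the granule genes Elane (2.78 ± 0.29) and Mpo (2.61 ± 0.37) higher. The 6 rising neutrophil markers had a median slope of 0.53 on the marker level (interval -0.10 to 0.97, 0.82 for a rise that follows in full). Dendritic cell markers rose in 2 of 7 cases and fell in 2, with a median of -0.23, a mean of 0.21 and a higher direction by camera (adjusted p = 0.961). Their median changed sign under 6 of 22 alternatives, with a range of -0.41 to 0.45. Erythroid and endothelial markers rose in 3 of 7 cases and fell in 1 (camera adjusted p = 0.4505). Glycolysis genes rose in 5 of 21 cases and fell in 7 (5 and 8 adjusted over the list alone; camera adjusted p = 0.178), with Hk3, a hexokinase gene, lower (-1.69 ± 0.08). Hypoxia genes rose in 9 of 20 cases and fell in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.158), with Ddit4 higher (1.93 ± 0.17), and 11 of 24 alternatives called the list higher. Ribosomal protein genes rose in 5 of 32 cases and fell in none (0 and 0 adjusted over the list alone; camera adjusted p = 0.630), and 7 of 24 alternatives called the list higher. Lymphoid markers had 4 tested members and no list test, with a median of -0.08, a mean of 0.05 and Cd4 higher (1.31 ± 0.17). In all, 17 of 30 lists were called by camera with the preset correlation, 9 higher and 8 lower. With an estimated correlation the calls that held were interferon response and cholesterol synthesis. The fry test, which does not set a list against other genes, differed for some lists. Its adjusted p passed 0.05 in the higher direction for uncalled lists: MHC class II (0.0454), cholesterol efflux (0.0163), hypoxia (0.00286) and adhesion (0.00424). For oxidative phosphorylation, which camera called, it was 0.0899. Counts for lists without a second pair of numbers were equal when adjusted over the list alone.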

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

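The filter on transwell FPKM and the GC and length correction without the block were chosen after the data were seen. The count of 5286 differing genes stayed within 1.5 times except with a mean FPKM of at least 5, which tests fewer genes (2674 in edgeR, 2696 in limma). Leaving out each library in turn gave 4042 to 5310 genes, 1824 to 2157 of at least 2-fold and 16 to 18 lists. The 2-fold count of 1997 was 342 with a mean FPKM of at least 5 and 548 with a mean transwell FPKM of at least 1, where fewer genes are tested. With limma it was 718 on log2(FPKM + 1), 718 without trend, 1023 and 869 with pseudocounts of 0.1 and 0.5, 755 without filter, 294 with a mean FPKM of at least 5, 689 with median-ratio scaling, 690 with TMM scaling and 611 after quantile normalization. A pseudocount shrinks the folds of low genes, and what else moved these counts was not tested. Called lists fell from 17 to 2 with an estimated correlation, and what in the test drove this fall was not examined. Genes called with both DESeq2 and edgeR numbered 5014, with 0 in opposite directions.

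The Notch list turned from higher to lower with a mean FPKM of at least 5 (median -0.29 in edgeR, -0.22 in limma) and with a mean transwell FPKM of at least 1 (-0.15), where members low in transwell libraries are left out. Over the lists under up to 24 alternatives each, estimated correlation aside, the call was the same 620 times, gained 44 times and lost 35 times with camera's direction kept, and in the 3 Notch cases it was lost with that direction turned. Among the 35 the Notch median was also below 0 in limma after quantile normalization (-0.04). For named genes it was the same 3233 times and lost 55 times. No named gene changed direction past the threshold. Some lists had under 5 tested members with other filters and gave no value there.

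Same-numbered libraries did not deviate together (correlations -0.083, -0.445 and 0.056), and no library correlated best with its own number. These values give no sign that the numbers pair the samples, but with 3 libraries per group they cannot exclude it. A replicate block gave 5124 genes, 1962 of at least 2-fold and 16 lists, and 5656, 1964 and 16 with the GC and length correction; the list no longer called was the unfolded protein and stress response (adjusted p = 0.0897, and 0.07195 with the correction). At these depths and with 3 libraries per group 41.79% of simulated 1.5-fold changes were recovered, and the part of depth was not tested. The simulation changed far fewer genes than were called in the data, so this share need not hold for them.

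Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many genes, 5286, and the highest other split gave 0 (edgeR, at most 1175 genes at an unadjusted p under 0.05, with the effect inside the spread of mixed groups). For 2-fold genes 1 gave 1997 and the highest other 0. For lists 1 gave 17 and the highest other 16. These splits are too few for a share under 0.05.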

Other observations

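The tests on pathways, on Xist and on the macrophage identity list, and the GC and length correction without the block, were chosen after the results were seen. Among pathways of the deposited annotation, ECM-receptor interaction and Hippo signaling had the smallest adjusted p, followed by Basal cell carcinoma, Lysosome and Steroid biosynthesis at an equal value (1.6e-04). Of 346 pathways 27 were higher and 29 lower in contact (camera, preset correlation), and 0 were called with an estimated correlation (smallest adjusted p 0.358, 37 at an unadjusted p under 0.05). In ECM-receptor interaction (adjusted p = 6.6e-11) 45 of 64 genes were higher and 8 lower. Of the 45 rising genes 27 had a mean transwell FPKM under 1. The median slope of the 45 on the epithelial marker level over the 3 contact libraries was 0.674, where 0.736 is predicted if the whole rise were carried over. Of the 64 genes 5 are on the epithelial list, from which the marker level was taken, so the slope is not wholly independent of it. The laminin receptor gene Itga3 (10.9 ± 3.28 against 0.0167 ± 0.0115 FPKM) and the matrix gene Tnc (12.1 ± 3.72 against 0.337 ± 0.211 FPKM) rose. In Hippo signaling (adjusted p = 4.8e-07) 65 of 134 genes were higher and 13 lower, with Wnt4 at 8.6 ± 2.72 against 0.0133 ± 0.0153 FPKM and Ajuba higher (3.57 ± 0.23). Of its rising genes 41 had a mean transwell FPKM under 1, and the median slope was 0.789 (0.828 predicted), with 2 of the 134 genes on the epithelial list. In Basal cell carcinoma 24 of 45 genes were higher and 5 lower, with a slope of 0.869 (0.878 predicted) and 0 genes on the epithelial list. In the lysosome pathway (57 of 126 lower, 8 higher, 31 in the fixed lists) the proton pump gene Atp6v0a1 (-0.88 ± 0.08) and Galns (-0.83 ± 0.08) fell.

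Epithelial genes stood high in all 3 contact libraries, with Krt5 at 376 ± 120 FPKM and a median log2 change of 8.985, although the cells had been sorted, and 25 of the 27 rising markers had a mean under 0.5 FPKM in transwell libraries. RNA of a cell of another origin is a candidate source: Xist, the female-specific transcript, was named after its values were seen and rose by 7.16 (3.16 ± 1.06 against 0.02 ± 0.01 FPKM). The Y-linked genes Ddx3y (0.41 ± 0.20), Uty (-0.14 ± 0.21), Kdm5d (-0.23 ± 0.16) and Eif2s3y (0.08 ± 0.17) missed the threshold. Attached or engulfed mEC25 cells, or their free RNA, could bring both, and these tables do not part them. Dissociation and sorting stress stays open too. Its list had a median of 0.4076, but some rising members, such as Klf4 and Hspa1b, followed the epithelial marker level, and others did so less. Carried-over RNA could raise this median as well, so it does not decide the question. Macrophages of both groups were sorted, but only those in contact had been mixed with tumor cells, and whether handling differed was not tested.

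The rises of inflammatory, cholesterol synthesis and proliferation genes may come from carried-over mEC25 RNA or from the macrophages themselves. Carried-over RNA would make the rising members follow the marker level, which varied 1.67-fold over the 3 contact libraries, and the tables argue against it as the whole source for inflammatory genes (median slope -0.1417, interval -0.24 to -0.037, 0.56 predicted) and cholesterol synthesis genes (-0.06332, interval -0.14 to -0.0043, 0.54 predicted). Proliferation genes had a slope of 0.905 (interval 0.80 to 0.99), above the 0.71 predicted. Random lists of unchanged genes of like level gave -0.13 to 0.12 (95% range). The rise thus followed the markers, as carried-over RNA of dividing cells would make it. That dividing macrophages bring part or all of the rise cannot be excluded with 3 contact libraries and no mEC25 profile in use. Intervals cover the choice of genes and not the spread of 3 libraries, and fibroblast markers, outside the marker level, had a slope of 0.60 (interval 0.37 to 0.86, 0.71 predicted). That cell contact raises Il1b and cholesterol synthesis in macrophages stays a hypothesis, as sorting stress was not excluded for these genes.

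The fall of interferon genes may reflect contact itself or dilution of macrophage RNA. Dilution would lower all macrophage genes alike, and the macrophage identity list had a median of 0.01861 (interval -0.35 to 0.31), above the interferon median of -1.324, for which 60.1% of the RNA would have to be foreign. TMM scaling sets most genes near 0 (median of all tested genes 0.02547), so a fall shared by most genes would not show in the identity median. Scaling moves both lists alike, so the gap between them does not rest on it. The 50 genes highest in transwell libraries had a median of -0.36. They were picked by their transwell level, which favours falls, so this value cannot tell whether dilution is part of the fall. Dilution as part of the fall stays open. GC content or length as the whole cause is argued against as well, since the median was -1.286 after the correction, and -1.289 with the replicate block. A lower interferon response in macrophages that touch the cancer cells, or a higher one across the transwell, is left as a hypothesis, and without macrophages cultured alone in these comparisons its direction cannot be assigned to either group.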
